A study of Solanum dulcamara with 16 samples.

How the data were processed

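Leaves of Solanum dulcamara plants grown from stem cuttings of 4 clones (Siethen, Erkner, Grunewald and Mehrow) under 16 h of light and 8 h of dark were the source of the RNA, per the labels. In the feeding group 2 third-instar larvae of Spodoptera exigua sat on the third leaf for 24 h. In the wounding groups that leaf received 4 rows of a pattern wheel and 20 µL of oral secretions and was harvested after 1 h or 24 h. The labels give no hour of the day. Each of the 16 arrays carried RNA of 6 plants, extracted with a plant RNA kit and DNase and labelled with 1 dye from an oligo-dT primer, per the labels. Arrays of different groups were matched by clone from their labels. The pairing was checked on the values: after subtracting group means, the 24 pairs of arrays of the same clone had correlations of 0.289 to 0.655, pairs of different clones at most 0.0856, and for 16 of 16 arrays the closest other array was of the same clone.

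The intensity values used here are processed spot signals that Agilent Feature Extraction (protocol GE1_1105_Oct12) had background-subtracted and detrended within each array but not scaled between arrays, per the file headers. Spot means, medians and local backgrounds in the same files are raw intensities, per the file headers. A deposited value table holds log2 values that the authors made with limma, no version or step being stated. From the values, that table equals the median spot signal after normexp correction and quantile normalization, within 0.0731. Each array held 62970 spots, of which 61651 were no controls, for 60151 probes on 28573 assembled contigs. In 5384 contigs the probes lie in both orientations. Annotation texts came from the array's own table, and 41218 probes carry a named one.

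Signals were put on the log2 scale, the array's 75th percentile of log2 signal was subtracted, replicate spots of a probe were averaged, and spots marked as outliers by Feature Extraction (7 to 34 per array) were left out. No spot was saturated. Probes well above background, by the mark in the files, on at least 3 of the 4 arrays of at least 1 group were kept, which left 47423 probes on 24202 contigs (17422 named) and removed 12728. Models were fitted with limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table: 1 mean per group over all 16 arrays, moderated t tests (eBayes), and adjustment by Benjamini and Hochberg over the kept probes, with calls at an adjusted p under 0.05. The probe was the unit of the counts. A contig was represented by its brightest probe for lists and named genes. Clones were compared by an F test in a model of group and clone. Fold changes of pairs of treatments were compared by Pearson correlation over kept probes, beside simulated groups without effect and splits of the control arrays between the comparisons.

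Contigs were sorted into 28 lists by patterns on their annotation texts, and each list was tested in 5 contrasts with camera at a preset correlation of 0.01, adjusted over all lists and contrasts. Where the call was lost with the correlation estimated from the data, that adjusted p is given too. Lists for vein and epidermis, clock, ribosomal proteins and reference genes were kept for tissue makeup, harvest hour and scaling. A slide is the glass that arrays share, read from the file headers.

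For each contrast the named genes were the 10 largest rises and the 10 largest falls among annotated probes with an adjusted p under 0.05, well above background on all 8 arrays and changed the same way in all 4 clones, 1 per contig and annotation text and none of unknown function. To these came up to 3 with the largest fold that could only be bounded, up to 4 members with the smallest p from each list described, and the 5 smallest p for clones. A gene named in one comparison may be given in another, and not all that the rule allows are printed. Genes outside this rule are said to be named after their values were seen. Where a group measured a contig on no array, with measured meaning that any of its probes was well above background, only a bound is given. It is the mean of the brighter group minus the mean, over the other group's arrays, of the larger of the signal and the lowest log2 signal of any probe well above background on that array. Such bounds applied to 144 contigs brighter after feeding and 10 brighter in the controls, the most of any comparison.

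The groups, tests, lists, naming rule and a set of alternatives were fixed before the data were examined. The alternatives were the clone as a block, slide as a fixed or random block, array weights, a trended and robust spread, quantile normalization, normexp correction (offset 50) with quantile normalization, the deposited table, no filter or a stricter one on dim probes, the 2 groups of a contrast alone, a 2-fold or a stricter p threshold, the mean over probes of a contig, other list tests (fry, estimated correlation), split controls, called probes alone for the similarities, and leaving out each array or clone. Fits within slide 1 and within slide 2, slide in the clone model, narrowed lists and the pair of feeding and wounding at 1 h were added after the data were seen.

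Precision is set by 4 arrays per group. The median background was 17 to 20 against 75th percentiles of 112.9 to 340.1, arrays of a group correlated at 0.943 to 0.963, and the closest pair of arrays in a group differed by a median of 0.23 (log2). Of 47404 simulated probes 200 were changed. Recovered were 5.97%, 43.3% and 89.4% of changes of 0.5, 1 and 2 (log2) with 1 false call. The camera p was 1.39e-14 for a shifted list and 0.377 for an unshifted one. A clone block gave 2.99%, 38.8% and 84.8% with 6 false calls, but raised calls in the real data, so its rates do not apply.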

Results

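Leaf transcripts of bittersweet nightshade, Solanum dulcamara, were measured on 16 single-colour arrays, 4 in each of 4 groups. The groups were undamaged controls, leaves on which Spodoptera exigua caterpillars (beet armyworm) fed for 24 h, and leaves wounded with a pattern wheel and treated with the caterpillars' oral secretions and harvested after 1 h or after 24 h. Every group held 1 array from each of 4 clones named Siethen, Erkner, Grunewald and Mehrow, and every array carried RNA pooled from 6 plants. The control plants had been harvested in equal parts at 1 h and at 24 h, and the labels do not say how these were spread over the control arrays. The 75th percentile of the processed signal ranged from 112.9 to 340.1 between arrays, and 69.2% to 81.4% of the probes lay well above background. Groups were spread unevenly over 3 slides, so results are also given with slide as a block and within slides 1 and 2. Within a slide the groups come in part from different clones, such as feeding in Grunewald against controls of Siethen and Erkner on slide 1, so those values also carry clone differences. In a principal component analysis, the first component (36.3% of the variance) parted feeding and wounding at 1 h (scores of 65.43 to 103.1) from control and wounding at 24 h (-100.3 to -64.28). The second component (19.6%) parted feeding (48.28 to 108.3) from wounding at 1 h (-100.1 to -77.91). Below, wounding stands for the wheel and the secretions together, the design held no wounding without secretions, and each value is a log2 difference ± SE with n = 4 arrays per group unless a fold is given. Lists of contigs by annotation were tested with camera, and counts over the list alone adjust p within the list.

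**Figure D1:**
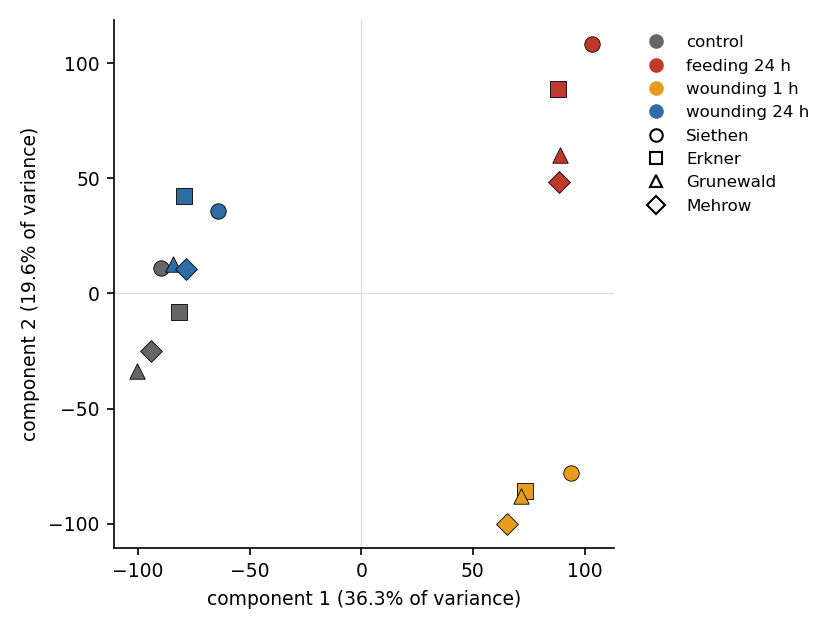
Scores of the 16 arrays on the first and second principal components of log2 signal (unitless), with colour for the group and shape for the clone. Feeding and wounding at 1 h lie at 65.43 to 103.1 on the horizontal axis, and control and wounding at 24 h at -100.3 to -64.28.

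Feeding was set against the undamaged leaves to ask which transcripts change where caterpillars eat. The classical anti-insect proteins of nightshades were among the largest rises. Proteinase inhibitor I (contig A_03677), which blocks digestive proteases in the insect gut, rose by 7.70 ± 0.47, and proteinase inhibitor II (A_16562), of the same use, by 6.04 ± 0.31. Polyphenol oxidase (C_03284) was at least 272-fold higher, a bound because no control array measured it well above background. A polygalacturonase-inhibiting protein (A_15310), which protects wall pectin, rose by 7.47 ± 0.45. A self-incompatibility-type S8 ribonuclease (A_03255) rose by 7.06 ± 0.52, and acetylornithine deacetylase (C_02707), an enzyme of arginine metabolism, by 7.96 ± 0.39, the largest rise among named contigs measured on all 8 arrays. Salicylic acid carboxyl methyltransferase (A_10948), which makes the volatile methyl salicylate, rose by 6.45 ± 0.49. A cytochrome P450 of the CYP81D family (A_07694) was at least 301-fold higher and a cytochrome P450 of the CYP81K family (A_00018) rose by 5.91 ± 0.37. All of these moved the same way in all 4 clones, and the adjusted p of the fitted ones lay between 3.84e-09 and 2.53e-07.

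The hormone pathway behind these defences rose with them. In the jasmonate biosynthesis list, 18 of 27 contigs rose and 1 fell (20 and 1 over the list alone, median 1.67, adjusted p = 5.32e-11). Without 7 contigs of other function 13 of 20 rose and 0 fell. The jasmonate enzyme 12-oxophytodienoate reductase 3 (A_10814) rose by 3.44 ± 0.13. Allene oxide synthase 2 (A_11142), which 3 of the 4 control arrays measured, rose by 7.11 ± 0.42, and OPC-8:0 CoA ligase (A_02806) by 2.12 ± 0.13. The faller of the 27, carotenoid cleavage dioxygenase 8 (A_11107, named after its values were seen), makes strigolactones. It was measured on 3 of the 4 control arrays and no feeding array. Among the JAZ/TIFY repressors, which jasmonate induces and which then damp it, 7 of 10 contigs rose and 2 fell (7 and 2 over the list alone, median 2.85, adjusted p = 2.28e-05). JAZ1 (C_01875) rose by 6.22 ± 0.32 and JAZ2 (C_01591) by 3.10 ± 0.15, whereas TIFY 4B (B_01730, -0.67 ± 0.20) and TIFY 8 (A_16963, -0.67 ± 0.10) fell, both named after their values were seen. With contigs that the controls did not measure set at their bound, the median of the JAZ/TIFY list was 2.35.

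Of the defence proteins themselves, 27 of 49 contigs rose and 5 fell (27 and 5 over the list alone) in the proteinase inhibitor list (median 0.55, adjusted p = 3.7e-07). Its fallers were 4 inter-alpha-trypsin inhibitor heavy chains with a RING finger (C_06638, C_04540, C_00054 and A_12766) and a nitrogen regulatory PII protein (A_05827). These were named after their values were seen, and none is a plant protease inhibitor by its Arabidopsis text. A metallocarboxypeptidase inhibitor (A_15279) rose by 3.05 ± 0.15, and a Kunitz trypsin inhibitor (A_02211) that 2 of the 4 control arrays measured rose by 9.78 ± 0.82. In the antinutritive enzyme list, 5 of 9 contigs rose and 2 fell (6 and 2 over the list alone, median 2.49, adjusted p = 0.00226, and adjusted p = 0.0654 with an estimated correlation). Besides C_03284 the risers were polyphenol oxidases DC_00892 (5.08 ± 0.33), C_02152 (2.67 ± 0.23) and C_03285 (at least 56.9-fold). Leucine aminopeptidase (A_03064, 2.49 ± 0.30) rose too, while threonine deaminase (A_16675, -0.58 ± 0.17) and an agmatinase (B_00944, -0.99 ± 0.19) fell, these 3 named after their values were seen. The terpene synthase list held 8 of 16 contigs that rose and 1 that fell (8 and 3 over the list alone, median 1.09, adjusted p = 0.000796, and adjusted p = 0.073 with an estimated correlation). Linalool synthase (A_08560) was at least 16.5-fold and an (E)-beta-ocimene synthase (A_06058) at least 40.6-fold higher, both makers of leaf volatiles. A germacrene D synthase (A_13223, -2.96 ± 1.04, measured on 2 of the 4 feeding arrays and named after its values were seen) fell. With unmeasured contigs at their bound the terpene median was 0.92.

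In the phenylpropanoid and lignin list, 34 of 74 contigs rose and 10 fell (34 and 12 over the list alone, median 0.35, adjusted p = 0.000114). Phenylalanine ammonia-lyase (C_00130), the entry to the pathway, stood at 2.56 ± 0.18 and hydroxycinnamoyl-CoA quinate transferase (C_06538) at 5.54 ± 0.41. In the phenolamide list, 9 of 20 contigs rose and 1 fell (9 and 5 over the list alone, median 0.052, adjusted p = 0.0324, and adjusted p = 0.107 with an estimated correlation). With the clone as a block its adjusted p was 0.0576. Ornithine decarboxylase (A_12222), which makes putrescine, rose by 3.24 ± 0.26, and a lysine or arginine decarboxylase (A_14044, -0.58 ± 0.14, named after its values were seen) fell. The flavonoid list did not pass, with 19 of 80 contigs up and 13 down (19 and 14 over the list alone, median 0.12, adjusted p = 0.0583). Its highest member by p, C_06686 (7.16 ± 0.26, measured on 3 of the 4 control arrays), carries the text anthocyanidin synthase in tomato and jasmonate-regulated gene 21 in Arabidopsis. Glutathione transferases, which detoxify, held 14 of 42 contigs that rose and 5 that fell (14 and 5 over the list alone, median 0.25, adjusted p = 0.0135, and adjusted p = 0.118 with an estimated correlation), such as C_01259 at 2.80 ± 0.19. Its fallers were A_01121, A_01002, C_02191, A_14310 and a thioredoxin-type contig (A_03825), named after their values were seen. In the steroid and glycoalkaloid list, 14 of 68 contigs rose and 20 fell (15 and 22 over the list alone, median -0.24, adjusted p = 0.728).

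In the WRKY list, 21 of 53 contigs rose and 3 fell (22 and 5 over the list alone, median 0.24, adjusted p = 0.000117, and adjusted p = 0.0654 with an estimated correlation). WRKY33-like C_04643 stood at 2.25 ± 0.16. Those that fell were C_05327 (-1.46 ± 0.22, measured on 2 of the 4 feeding arrays), C_00658 (-2.08 ± 0.29) and A_14723 (-0.41 ± 0.12). They were named after their values were seen, and the last is a SIN3-like corepressor by its other texts. In the calcium signalling list, 65 of 258 contigs rose and 23 fell (65 and 22 over the list alone, median 0.087, adjusted p = 0.00518, and adjusted p = 0.0654 with an estimated correlation). A calmodulin-binding protein (A_08339) was at least 8.8-fold higher. In the ethylene list, 48 of 159 contigs rose and 20 fell (49 and 21 over the list alone, median -0.043, mean 0.46, test upward with adjusted p = 0.00525, and adjusted p = 0.0654 with an estimated correlation). ERF4 (C_04225, measured on 3 of the 4 control arrays) rose by 5.22 ± 0.20. In the abscisic acid and water deficit list, 47 of 168 contigs rose and 26 fell (47 and 27 over the list alone, median 0.066, adjusted p = 0.0477, and adjusted p = 0.0907 with an estimated correlation). Its adjusted p was 0.0553 with the clone as a block and 0.0816 under normexp correction. Sugar transporters and invertases, which steer carbon between organs, held 28 of 116 contigs that rose and 18 that fell (29 and 18 over the list alone, median 0.12, adjusted p = 0.0382, and adjusted p = 0.0654 with an estimated correlation). A SWEET-type MtN3 transporter (A_14975) rose by 2.81 ± 0.20. The auxin list held 30 of 133 contigs that rose and 37 that fell (32 and 39 over the list alone, median -0.076, mean 0.088, test upward with adjusted p = 0.829). A GH3 auxin-conjugating enzyme (C_04343) was at least 21.8-fold higher, and a SAUR growth gene (DC_00031) stood at -2.43 ± 0.19. Pathogenesis-related proteins went both ways, with 26 of 95 contigs up and 24 down (26 and 25 over the list alone, median -0.091, mean 0.28, test upward with adjusted p = 0.664). An osmotin (A_03222) was at least 10.2-fold higher and a thaumatin (C_02068, -1.91 ± 0.14) lower. In the heat shock and chaperone list, 62 of 283 contigs rose and 44 fell (62 and 44 over the list alone, median 0.032, adjusted p = 0.0603), with a DNAJ chaperone (A_02259) at 3.16 ± 0.13.

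The photosynthetic apparatus fell. In the photosynthesis list, 11 of 132 contigs rose and 94 fell (11 and 97 over the list alone, median -0.81, adjusted p = 1.05e-11, and adjusted p = 0.135 with an estimated correlation). Among them was a PsbP protein of photosystem II (A_01615, -1.48 ± 0.13). Without 34 contigs of other function 6 of 98 rose and 81 fell. In the tetrapyrrole list, which holds the makers of chlorophyll, 1 of 19 contigs rose and 16 fell (1 and 16 over the list alone, median -1.30, adjusted p = 3.78e-07, and adjusted p = 0.0784 with an estimated correlation). Protochlorophyllide reductase (A_12207) fell by 3.29 ± 0.40. Magnesium-protoporphyrin methyltransferase (A_07441) fell by 2.12 ± 0.17 and magnesium chelatase subunit I (A_00695) by 1.77 ± 0.18. The member that rose was a glutamyl-tRNA reductase (A_14912, 2.28 ± 0.18). From chlorophyll breakdown, a stay-green protein (A_09253), which removes magnesium from chlorophyll, was at least 77.5-fold higher and pheophytinase (A_15832), which cleaves the phytol tail, rose by 5.36 ± 0.23. The list of chlorophyll breakdown and senescence as a whole did not pass, with 9 of 39 contigs up and 7 down (10 and 7 over the list alone, median 0.20, adjusted p = 0.164). Chlorophyllide a oxygenase on it (A_04286), which makes chlorophyll b, fell by 1.67 ± 0.19. Among the largest falls were polygalacturonase 2 (A_13623), which loosens pectin, by 3.27 ± 0.21, gibberellin 20-oxidase 1 (C_04267), which makes active gibberellin, by 3.19 ± 0.34, and a germin-like oxalate oxidase (A_02104) by 4.47 ± 0.36, the largest fall among named contigs. A contig annotated wound-induced protein (A_15957) fell by 3.87 ± 0.47, against its name.

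In the cell wall list, 30 of 181 contigs rose and 54 fell (30 and 59 over the list alone, median -0.21, adjusted p = 0.418). The histone and cell cycle list held 14 of 157 contigs that rose and 31 that fell (13 and 31 over the list alone, median -0.17, adjusted p = 0.303), such as a D3 cyclin (DC_00335) at -2.03 ± 0.15. In the clock and time-of-day list, 21 of 122 contigs rose and 53 fell (22 and 55 over the list alone, median -0.49, adjusted p = 0.0136). That list also caught GDSL acylhydrolases through the letters LHY. Without the 53 contigs of other function (a narrowing made after the values were seen) 9 of 69 rose and 32 fell (median -0.52, adjusted p = 0.00403). None of the lists kept for tissue makeup and scaling passed. Vascular markers held 17 of 88 contigs up and 16 down (18 and 17 over the list alone, median 0.073, adjusted p = 0.334), and epidermis and trichome markers 32 of 163 contigs up and 42 down (34 and 43 over the list alone, median -0.14, mean 0.16, test downward with adjusted p = 0.975). Cytosolic ribosomal proteins held 6 of 153 contigs up and 17 down (4 and 10 over the list alone, median -0.17, adjusted p = 0.134) and the reference genes 15 of 145 contigs up and 29 down (15 and 28 over the list alone, median -0.12, adjusted p = 0.533).

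In all, 17045 of 47423 probes differed between feeding and control, 7613 higher and 9432 lower, which made 8628 contigs. With slide as a fixed block 17456 probes were called, and within slide 1 and slide 2, where fewer arrays enter, 3334 (1917 higher, 1417 lower) and 10734 (4965 and 5769). Of those changed at least 2-fold 3909 were higher and 3905 lower. Within the same slides the list medians were 2.13 and 1.68 for jasmonate biosynthesis, 2.93 and 2.96 for JAZ/TIFY, 0.55 and 0.94 for proteinase inhibitors, 2.69 and 2.49 for antinutritive enzymes and 1.48 and 1.16 for terpene synthases. They were 0.36 and 0.36 for phenylpropanoids, -0.51 and -0.89 for photosynthesis, -1.20 and -1.44 for tetrapyrroles and -0.49 and -0.60 for the clock. The rest had 0.28 and 0.38 for WRKY factors, 0.076 and 0.097 for calcium, 0.10 and 0.0073 for ethylene, 0.17 and 0.34 for glutathione transferases, 0.053 and 0.21 for abscisic acid, 0.022 and 0.13 for sugar transport and 0.14 and 0.26 for phenolamides. With slide as a block the jasmonate median was 1.66, the photosynthesis median -0.79 and the ethylene median -0.079.

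Wounding with oral secretions, 24 h before, was set against the controls to ask what a dosed imitation of herbivory leaves behind after a day. Fewer transcripts were called than after feeding, and defence proteins were among those that rose. Proteinase inhibitor I (A_03677) rose by 4.44 ± 0.47, proteinase inhibitor II (A_16562) by 3.12 ± 0.31, and the S8 ribonuclease (A_03255) by 3.08 ± 0.52. A peroxidase (A_07748), an enzyme that can crosslink walls, rose by 3.78 ± 0.27. A Kunitz trypsin inhibitor (A_01942) was at least 7.12-fold and a T2 ribonuclease (A_10269) at least 9.09-fold higher, neither well above background on any control array. The same held for the heat stress factor HSFB3 (C_06455), at least 7.87-fold. A class IV chitinase (A_12117), which 1 of the 4 control arrays measured, rose by 4.59 ± 0.26, and an LEA4 protein of drying seeds (A_05928) by 3.75 ± 0.56. Other risers were an AINTEGUMENTA-type AP2 factor (C_05169, 3.34 ± 0.23), which promotes organ growth, and a glycine-rich wall protein (A_13249, 3.25 ± 0.28). An LSD1-type zinc finger (A_13898), a kind of cell death regulator, rose by 3.57 ± 0.29 and a BRO1-domain protein (A_02764) by 3.25 ± 0.20. Sucrose phosphate synthase (A_08661), which makes sucrose in leaves, fell by 1.21 ± 0.25, a group I WRKY factor (C_00658) by 1.43 ± 0.29 and a chloroplast Ycf2 transcript (A_05439) by 1.18 ± 0.24. Adjusted p lay between 4.78e-07 and 0.0283 for the fitted ones, each of which moved the same way in all 4 clones.

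By groups, 4 of 49 contigs rose and 0 fell (13 and 1 over the list alone) among proteinase inhibitors (median 0.30, adjusted p = 3.57e-05, and adjusted p = 0.0654 with an estimated correlation). The fourth riser was a Kunitz inhibitor (A_16435, 2.10 ± 0.42, measured on 2 of the 4 control arrays). With unmeasured contigs at their bound the median was 0.24. Among glutathione transferases 4 of 42 contigs rose and 0 fell (11 and 3 over the list alone, median 0.27, adjusted p = 5.41e-05), all of the tau class, with A_15764 at 1.49 ± 0.27. Pathogenesis-related proteins held 5 of 95 contigs that rose and 0 that fell (8 and 2 over the list alone, median 0.04, adjusted p = 0.0204, and adjusted p = 0.0654 with an estimated correlation). Besides the chitinase these were thaumatins A_08898 (1.12 ± 0.19) and A_13374 (1.41 ± 0.31, measured on 2 of the 4 control arrays and named after its values were seen), a glucanase (C_02258, 1.16 ± 0.16) and an STS14-type protein (A_11101, 1.34 ± 0.27). In the phenolamide list 1 of 20 contigs rose and 0 fell (2 and 0 over the list alone, median 0.22, adjusted p = 0.0127, and adjusted p = 0.0784 with an estimated correlation). Its riser was a tyramine feruloyltransferase (A_03687), at least 1.35-fold higher. In the histone and cell cycle list 3 of 157 contigs rose and 1 fell (21 and 3 over the list alone, median 0.058, adjusted p = 0.00256, and adjusted p = 0.073 with an estimated correlation). Its risers were cyclin D3 (C_00577, 1.13 ± 0.16), a B2-type cyclin-dependent kinase (A_03996, 1.11 ± 0.21) and cyclin B1 (A_15475, at least 1.63-fold). The faller was a cycling DOF factor (A_11191, -1.69 ± 0.31, measured on 2 of the 4 wounded arrays), which belongs to flowering time. The jasmonate biosynthesis list was shifted without a contig called in the model without clones (median 0.26, adjusted p = 0.0272, and adjusted p = 0.229 with an estimated correlation), with 5 at an unadjusted p under 0.05 in limma. With the clone as a block 4 of its contigs rose, an allene oxide cyclase (A_00305), a lipoxygenase (A_06880) and the PLAT/LH2 proteins C_03499 and C_03498, named after their values were seen. Without its 7 contigs of other function, left out after the values were seen, adjusted p was 0.126. No JAZ/TIFY contig was called (median 0.045, adjusted p = 0.418, 3 at an unadjusted p under 0.05 in limma). Nor was any of the terpene synthases (median -0.21, adjusted p = 0.782, 4 so), antinutritive enzymes (median 0.15, adjusted p = 0.334, 3 so, 2 higher over the list alone) or tetrapyrrole contigs (median 0.018, adjusted p = 0.421, 2 so). The clone block called ocimene synthases A_14420 and C_01516 and serine or threonine dehydratases A_15036 and A_16675 (also those over the list alone) higher and magnesium chelatase subunit D (C_02106) lower, named after their values were seen, and 0 JAZ/TIFY contigs. In the photosynthesis list, 0 of 132 contigs rose and 1 fell (0 and 2 over the list alone, median -0.057, adjusted p = 0.539), namely a light-harvesting-like protein 3 (C_02477, -0.58 ± 0.13).

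The phenylpropanoid list held 1 of 74 contigs that rose and 0 that fell (3 and 2 over the list alone, median 0.098, adjusted p = 0.0525), and adjusted p = 0.0241 with the clone as a block. Its riser was a caffeoyl-CoA methyltransferase (C_01732, 1.83 ± 0.36). In the epidermis and trichome list, 4 of 163 contigs rose and 0 fell (5 and 0 over the list alone, median 0.009, adjusted p = 0.0516), and adjusted p = 0.0358 with the clone as a block. The risers were lipid transfer proteins A_16982 (1.09 ± 0.22) and A_07337 (0.82 ± 0.18) and GDSL lipases A_15716 (1.24 ± 0.23) and A_04350 (0.88 ± 0.16). In the cell wall list, 5 of 181 contigs rose and 3 fell (6 and 4 over the list alone, median 0.002, adjusted p = 0.248). Expansin 1 (C_06357), which loosens walls, rose by 1.87 ± 0.37 and a pectate lyase (C_05683, measured on 1 of the 4 control arrays) by 4.44 ± 0.45. The other risers were an expansin-like protein (A_03857), a pistil extensin-like protein (A_14216) and the proline-rich C_04446. The fallers were a xyloglucan endotransglucosylase (DC_01297) and 2 contigs with condensin and RING finger texts (A_14509 and A_16469), some of these named after their values were seen. Cytosolic ribosomal proteins were shifted without a called contig (median 0.22, adjusted p = 6.74e-12, and adjusted p = 0.257 with an estimated correlation), with 40 at an unadjusted p under 0.05 in limma and 6 higher with the clone as a block. Reference genes were shifted with 1 of 145 contigs up and 1 down (1 and 1 over the list alone, median 0.059, adjusted p = 0.00949, and adjusted p = 0.073 with an estimated correlation), namely an actin-binding glycine-rich protein (A_03562) and a gamma-tubulin complex component (B_02539). The vascular markers had no call over all probes (median 0.017, adjusted p = 0.182, 22 at an unadjusted p under 0.05), and with the clone as a block 9 were higher and 4 lower. Over the list alone a xylem cysteine peptidase (C_06274), laccase-like A_02530 and subtilase A_10420 were higher and laccase-like C_05855 and subtilase A_10862 lower, named after their values were seen. In the WRKY list, 3 of 53 contigs rose and 1 fell (4 and 5 over the list alone, median 0.025, mean -0.0083, test upward with adjusted p = 0.641). WRKY23-like A_03739 stood at 2.01 ± 0.21, WRKY1a-like A_00080 (measured on 2 of the 4 control arrays) at 2.57 ± 0.33 and WRKY71-like C_04899 at least 1.42-fold higher. In the clock list, 3 of 122 contigs rose and 0 fell (3 and 0 over the list alone, median -0.021, test upward with adjusted p = 0.267). These were the GDSL lipases A_15716 and A_04350 and the circadian clock coupling factor ZGT (C_06797, 1.52 ± 0.22).

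In all, 546 probes differed, 437 higher and 109 lower, in 288 contigs, and 9762 had an unadjusted p under 0.05. With the clone as a block 3398 were called, 2008 higher and 1390 lower. The count fell to 361 and 322 without control Erkner or Grunewald (29 and 35 lower), and to 342, 332 and 358 without wounded Siethen, Erkner or Grunewald (55, 33 and 51 lower). Without the clones Siethen, Erkner, Grunewald and Mehrow it was 264, 208, 226 and 289 (31, 6, 13 and 42 lower). Normexp background correction with quantile normalization gave 703, of which 453 were higher and 250 lower, and array weights 1348, of which 892 were higher and 456 lower. A fixed block for slide gave 438, within slide 1 alone 3 and within slide 2 alone 13. Within these slides the list medians were 0.18 and 0.38 for proteinase inhibitors, 0.20 and 0.34 for glutathione transferases, 0.087 and 0.12 for pathogenesis-related proteins, 0.28 and 0.11 for phenolamides. They were 0.11 and 0.025 for histones and cell cycle, 0.052 and 0.16 for jasmonate biosynthesis, 0.34 and 0.11 for ribosomal proteins and 0.08 and 0.0043 for reference genes. Slide as a block gave medians of 0.28 for proteinase inhibitors, 0.24 for glutathione transferases and 0.13 for phenolamides.

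Wounding with oral secretions 1 h before was set against the controls to ask how the response starts. Jasmonate genes were among the largest early rises. JAZ1 (C_01875) rose by 7.18 ± 0.32, and JAZ8-like TIFY 5A (C_05287) was at least 220-fold higher. A CYP94B fatty acid hydroxylase (C_02462), of the family that inactivates the jasmonate-isoleucine hormone, rose by 5.54 ± 0.36, and a peroxisomal 3-ketoacyl-CoA thiolase (A_05722), which shortens the jasmonate precursor, by 5.10 ± 0.21. Lipoxygenase 3 (A_04258), the step that adds oxygen to linolenic acid, rose by 4.39 ± 0.25. Allene oxide synthase A_13631, measured on 2 of the 4 control arrays, rose by 9.08 ± 0.49. The polygalacturonase-inhibiting protein (A_15310) rose by 6.02 ± 0.45, a cytokinin oxidase (A_12406), which destroys the growth hormone cytokinin, by 5.47 ± 0.30. The LEA4 protein (A_05928) rose by 5.37 ± 0.56, a lactoylglutathione lyase (C_03339) by 5.31 ± 0.23 and tryptophan synthase beta chain (A_09635) by 4.93 ± 0.59. The CYP81D enzyme (A_07694) was at least 148-fold higher and an auxin-regulated protein (A_08045) at least 66.8-fold. A MYB48-like factor (A_16973) fell by 2.82 ± 0.28, a cytokinin-responsive GATA factor (C_06700) by 2.58 ± 0.27. A cell wall and vacuolar invertase inhibitor (A_08571) fell by 2.57 ± 0.36 and the SAUR gene DC_00031 by 2.46 ± 0.19. Adjusted p of the fitted genes lay between 4.14e-10 and 6.85e-05, and each moved the same way in all 4 clones.

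In the jasmonate biosynthesis list, 13 of 27 contigs rose and 1 fell (15 and 1 over the list alone, median 1.16, adjusted p = 9.22e-08). The faller was a JAR-type jasmonate-conjugating enzyme (A_08949, -0.45 ± 0.13, named after its values were seen). Among JAZ/TIFY repressors 8 of 10 contigs rose and 1 fell (8 and 1 over the list alone, median 2.84, adjusted p = 1.98e-07). TIFY 8 (A_16963, -0.70 ± 0.10, also named after its values were seen) fell, and with unmeasured contigs at their bound the median was 2.72. In the ethylene list, 48 of 159 contigs rose and 18 fell (51 and 20 over the list alone, median 0.19, adjusted p = 5.41e-05), with ERF4 (A_09626) at 3.66 ± 0.14. In the WRKY list, 18 of 53 contigs rose and 10 fell (19 and 10 over the list alone, median 0.27, adjusted p = 0.000333, and adjusted p = 0.0691 with an estimated correlation). The smallest p was that of a jasmonate-induced WRKY (A_16053, 3.74 ± 0.16). In the calcium list, 63 of 258 contigs rose and 32 fell (65 and 34 over the list alone, median -0.0038, mean 0.30, test upward with adjusted p = 0.00518, and adjusted p = 0.0654 with an estimated correlation). An EF-hand calmodulin (C_05289) rose by 3.76 ± 0.20. Phenylpropanoid enzymes held 24 of 74 contigs that rose and 6 that fell (25 and 7 over the list alone, median 0.21, adjusted p = 0.000184), with 4-coumarate CoA ligase C_06281 at 2.98 ± 0.19. Terpene synthases held 7 of 16 contigs that rose and 1 that fell (7 and 1 over the list alone, median 0.58, adjusted p = 0.00168, and adjusted p = 0.0844 with an estimated correlation). Linalool synthase (A_08560) was at least 34.1-fold higher, and an exostosin-family contig (A_16212, -0.59 ± 0.20, named after its values were seen) fell. In the abscisic acid list, 44 of 168 contigs rose and 25 fell (45 and 28 over the list alone, median -0.047, mean 0.35, test upward with adjusted p = 0.0332, and adjusted p = 0.0793 with an estimated correlation). Among antinutritive enzymes 4 of 9 contigs rose and 0 fell (4 and 0 over the list alone, median 0.71, adjusted p = 0.0283, and adjusted p = 0.13 with an estimated correlation), and normexp correction gave adjusted p = 0.101. These were polyphenol oxidases C_02152 (1.76 ± 0.23) and DC_00892 (1.89 ± 0.33), leucine aminopeptidase (A_03064, 1.60 ± 0.30, named after its values were seen) and C_03284, which was measured on 3 of the 4 wounded arrays and on no control array. In the clock list, 9 of 122 contigs rose and 37 fell (9 and 39 over the list alone, median -0.32, adjusted p = 0.0101). In its narrowed form 3 of 69 rose and 28 fell (median -0.51, adjusted p = 8.07e-05). The risers were a contig annotated timing of CAB expression (A_13156) and CONSTANS-like A_15353 and C_00174, named after their values were seen.

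Proteinase inhibitors were not shifted as a group at 1 h: 8 of 49 contigs rose and 4 fell (8 and 4 over the list alone, median 0.0028, adjusted p = 0.214). Proteinase inhibitor I (A_03677) itself rose by 2.91 ± 0.47 and proteinase inhibitor II (A_16562) by 1.67 ± 0.31. Those that fell were 3 of the inter-alpha-trypsin inhibitor heavy chains (C_06638, C_04540 and C_00054) and an ACT-domain protein annotated uridylyltransferase PII (A_12900), named after their values were seen. Photosynthesis did not pass, with 5 of 132 contigs up and 6 down (1 and 3 over the list alone, median -0.11, adjusted p = 0.642). Tetrapyrroles did not either, with 2 of 19 contigs up and 3 down (1 and 3 over the list alone, median 0.023, adjusted p = 0.639). The photosynthesis contigs that rose carry other functions in part, namely ferredoxin 3 (DC_00304 and DC_00305), a glutamate synthase (A_01619), a uridine kinase (A_12808) and a chaperonin (A_04527), all named after their values were seen. Of the tetrapyrrole contigs, a uroporphyrinogen decarboxylase (A_06085) rose, while A_04226, a protochlorophyllide reductase (A_02740) and a uroporphyrinogen III synthase (A_15720) fell, some of them named after their values were seen. The glutamyl-tRNA reductase A_14912 on that list rose by 3.65 ± 0.18 and pheophytinase (A_15832) by 3.98 ± 0.23. Heat shock proteins held 45 of 283 contigs that rose and 26 that fell (44 and 26 over the list alone, median 0.02, adjusted p = 0.0661), and adjusted p = 0.0474 with the clone as a block. Ribosomal proteins held 21 of 153 contigs that rose and 0 that fell (2 and 0 over the list alone, median 0.28, adjusted p = 3.77e-08, and adjusted p = 0.385 with an estimated correlation). The vascular list (median 0.015, adjusted p = 0.259) and the reference genes (median -0.088, adjusted p = 0.728) did not pass, nor did the epidermis list (median -0.062, test upward with adjusted p = 0.562).

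In all, 12838 probes differed, 5611 higher and 7227 lower, in 6460 contigs. A fixed slide block gave 11870, and within slide 1 and slide 2 alone 3316 (2025 higher, 1291 lower) and 5398 (3426 and 1972). At 2-fold or more 3553 were higher and 2237 lower. Within slides the medians were 1.20 and 1.40 for jasmonate biosynthesis, 2.66 and 3.15 for JAZ/TIFY, 0.014 and 0.35 for ethylene, 0.074 and 0.31 for WRKY factors and 0.025 and 0.076 for calcium. They were 0.23 and 0.32 for phenylpropanoids, 0.88 and 0.69 for terpene synthases, 1.62 and 0.61 for antinutritive enzymes, -0.094 and 0.06 for abscisic acid, -0.34 and -0.35 for the clock and 0.56 and 0.084 for ribosomal proteins. With slide as a block the jasmonate median was 1.17 and the clock median -0.32, while the medians of antinutritive enzymes, WRKY factors and calcium genes moved to 1.27, 0.12 and 0.0025.

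**Figure D2:**
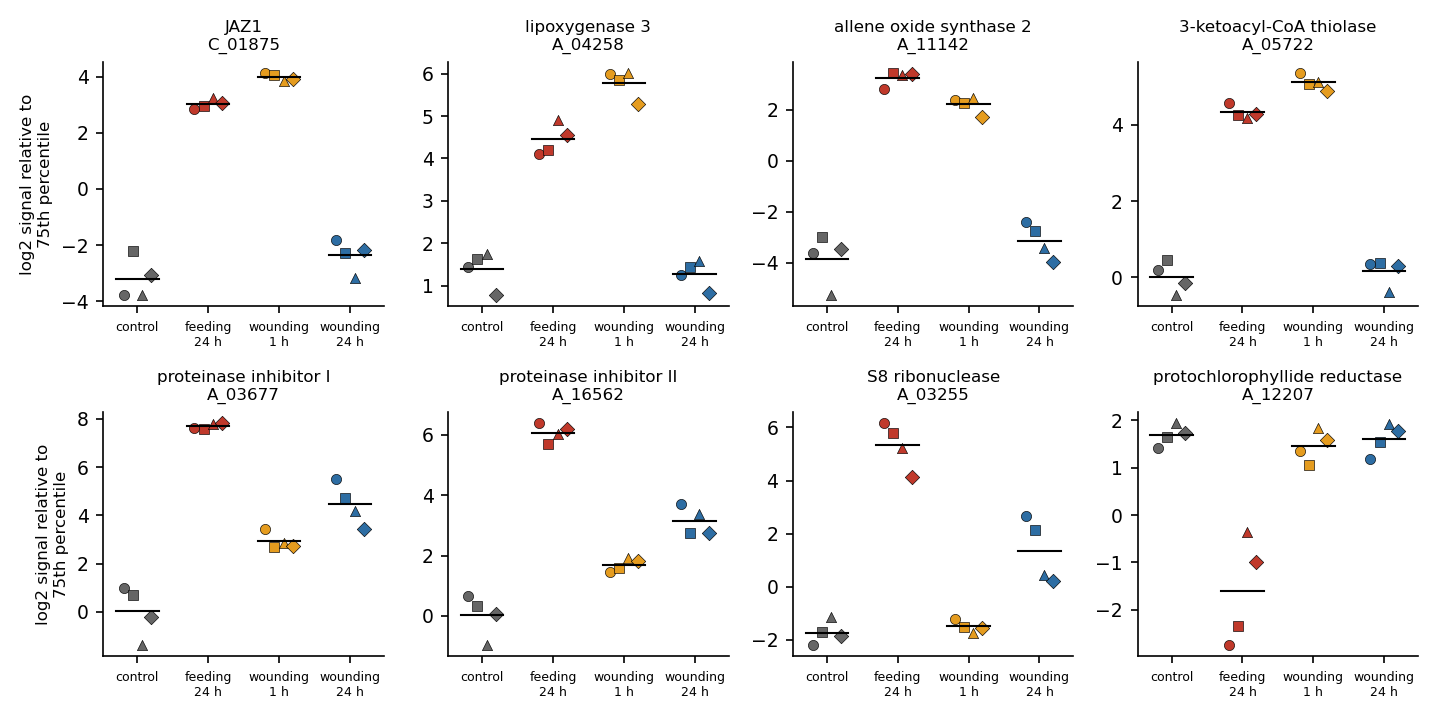
Log2 signal relative to each array's 75th percentile for 8 contigs, with a point for each of the 4 clones in each group and a line at the group mean. JAZ1 (C_01875) and lipoxygenase 3 (A_04258) stood high after feeding and at 1 h, proteinase inhibitors I (A_03677) and II (A_16562) were high at 24 h in both treatments, and protochlorophyllide reductase (A_12207) was low after feeding.

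Feeding was set against wounding at 24 h to ask where they part. Larvae stayed 24 h and wounding was done once, so kind and timing of damage mix. Allene oxide synthase 2 (A_11142) was higher by 6.40 ± 0.42, a Kunitz trypsin inhibitor (A_02211) by 7.17 ± 0.82, the polygalacturonase-inhibiting protein (A_15310) by 6.94 ± 0.45 and salicylic acid carboxyl methyltransferase (A_10948) by 5.99 ± 0.49. A hexenol acetyltransferase (A_12294), which makes the green-leaf volatile hexenyl acetate, was higher by 6.62 ± 0.37, and an acyltransferase with wax synthase homology (A_10079) by 7.79 ± 0.75. Polyphenol oxidase (C_03284) was at least 416-fold, the stay-green protein (A_09253) at least 126-fold and TIFY 5A (C_05287) at least 96.2-fold higher. Lower were the germin-like protein (A_02104, -4.54 ± 0.36), a second protochlorophyllide reductase (C_02805, -3.43 ± 0.37), a proline-rich extensin-like protein (C_04446, -3.55 ± 0.64) and gibberellin 20-oxidase 1 (C_04267, -3.06 ± 0.34). Adjusted p of the fitted genes lay between 2.42e-08 and 0.000582, with the same direction in all 4 clones.

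The jasmonate list held 15 of 27 contigs higher and 1 lower (16 and 1 over the list alone, median 1.44, adjusted p = 2.79e-09), the lower one a PLAT/LH2 protein (C_03499). JAZ/TIFY repressors held 7 of 10 contigs higher and 1 lower (7 and 2 over the list alone, median 2.48, adjusted p = 3.36e-05), the lower one TIFY 8 (A_16963), and both of these were named after their values were seen. Proteinase inhibitors held 16 of 49 contigs higher and 4 lower (17 and 4 over the list alone, median 0.51, adjusted p = 0.000343, and adjusted p = 0.0875 with an estimated correlation). Antinutritive enzymes held 5 of 9 contigs higher and 2 lower (6 and 2 over the list alone, median 1.78, adjusted p = 0.00827, and adjusted p = 0.0844 with an estimated correlation). Terpene synthases held 9 of 16 contigs higher and 1 lower (9 and 2 over the list alone, median 1.01, adjusted p = 0.000227, and adjusted p = 0.0654 with an estimated correlation). WRKY factors held 20 of 53 contigs higher and 1 lower (21 and 1 over the list alone, median 0.43, adjusted p = 4.78e-05, and adjusted p = 0.0578 with an estimated correlation). Phenylpropanoid enzymes held 28 of 74 contigs higher and 11 lower (29 and 11 over the list alone, median 0.47, adjusted p = 0.00033), and ethylene genes 50 of 159 contigs higher and 26 lower (52 and 28 over the list alone, median 0.30, adjusted p = 0.0023, and adjusted p = 0.0561 with an estimated correlation). Calcium genes held 63 of 258 contigs higher and 24 lower (66 and 25 over the list alone, median 0.17, adjusted p = 0.0057, and adjusted p = 0.0654 with an estimated correlation). The abscisic acid list held 46 of 168 contigs higher and 17 lower (47 and 20 over the list alone, median 0.22, adjusted p = 0.0279, and adjusted p = 0.073 with an estimated correlation). Flavonoid genes did not pass (median 0.27, adjusted p = 0.071), though with the clone as a block adjusted p was 0.0393. Members lower after feeding, all named after their values were seen, were C_04540, C_00054, A_12766 and A_05827 on the inhibitor list. Of the same kind were threonine deaminase (A_16675) and agmatinase (B_00944) on the antinutritive list, the exostosin contig (A_16212) on the terpene list and C_05327 on the WRKY list. The antinutritive members higher were those that rose against control. On the lower side stood photosynthesis with 5 of 132 contigs higher and 80 lower (6 and 83 over the list alone, median -0.70, adjusted p = 1.94e-12, and adjusted p = 0.118 with an estimated correlation). So did tetrapyrroles, with 1 of 19 contigs higher and 16 lower (1 and 17 over the list alone, median -1.22, adjusted p = 9.25e-09, and adjusted p = 0.0654 with an estimated correlation), the higher one being the glutamyl-tRNA reductase A_14912. The clock list held 20 of 122 contigs higher and 50 lower (20 and 55 over the list alone, median -0.34, adjusted p = 0.0023). The photosynthesis contigs higher after feeding were a sucrase-type ferredoxin (A_17042), ferredoxin 3 (A_16771), glutamate synthase (A_01619), uridine kinase (A_12808) and a root-type ferredoxin reductase (A_04587), named after their values were seen. Histones and cell cycle genes held 13 of 157 contigs higher and 54 lower (15 and 57 over the list alone, median -0.30, adjusted p = 0.00269, and adjusted p = 0.073 with an estimated correlation), with cyclin A1 (A_16024) at -2.16 ± 0.21. Ribosomal proteins held 7 of 153 contigs higher and 84 lower (8 and 93 over the list alone, median -0.45, adjusted p = 1.3e-08, and adjusted p = 0.37 with an estimated correlation). Reference genes held 8 of 145 contigs higher and 40 lower (8 and 40 over the list alone, median -0.13, adjusted p = 0.0252, and adjusted p = 0.0907 with an estimated correlation), a call that quantile normalization (adjusted p = 0.0892), normexp correction (0.0836) and the deposited table (0.0538) did not give. The vascular list (median 0.10, adjusted p = 0.817) and the epidermis list (median -0.088, mean 0.035, test downward with adjusted p = 0.442) did not pass.

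In all, 15164 probes differed, 6318 higher after feeding and 8846 lower, in 7598 contigs. A fixed block for slide gave 13714, and within slide 1 and slide 2 alone 3586 (1821 higher, 1765 lower) and 3529 (1837 and 1692). At 2-fold or more 3357 were higher and 3404 lower. Within slides the medians were 2.08 and 1.31 for jasmonate biosynthesis, 2.62 and 2.82 for JAZ/TIFY, 0.38 and 0.64 for proteinase inhibitors, 1.86 and 0.77 for terpene synthases and 0.48 and 0.36 for WRKY factors. They were 0.39 and 0.19 for phenylpropanoids, -0.35 and -0.92 for photosynthesis, -1.07 and -1.45 for tetrapyrroles, -0.38 and -0.20 for histones and cell cycle and -0.64 and -0.33 for ribosomal proteins. Under a slide block the photosynthesis median was -0.64.

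The 2 wounding groups were set against each other to ask what differs between 1 h and 24 h. The labels give no hour of the day, so a difference in harvest hour between the times is not excluded. Lower at 24 h were JAZ1 (C_01875, -6.34 ± 0.32), allene oxide synthase 2 (A_11142, -5.36 ± 0.42) and the CYP94B enzyme (C_02462, -5.40 ± 0.36), and TIFY 5A (C_05287) was at least 358-fold lower. So were an IAA-amino acid hydrolase (A_14342, -6.17 ± 0.28), of an enzyme family that frees conjugated hormones, a laccase or ascorbate oxidase (A_14239, -6.93 ± 0.38) and a DREB1A-like cold-response factor (A_02734, at least 55.6-fold). Higher at 24 h were a bacterial-induced peroxidase (A_13093, 3.81 ± 0.28), a dehydrin (A_14020, 3.16 ± 0.79), which protects drying cells, and the S8 ribonuclease (A_03255, 2.85 ± 0.52). So were expansin 1 (C_06357, 2.65 ± 0.37), a xyloglucan endotransglucosylase (C_02283, 2.55 ± 0.29) and the MYB48-like factor (A_16973, 2.65 ± 0.28). Adjusted p of the fitted genes lay between 1.42e-09 and 0.00693, with the same direction in all 4 clones. A heat shock cognate 70 protein (A_15179) rose by 2.04 ± 0.18 at 1 h and was called lower than control at 24 h, a difference of -3.04 ± 0.18 between the times.

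By groups, the jasmonate list held 2 of 27 contigs higher and 13 lower (2 and 13 over the list alone) at 24 h (median -0.77, adjusted p = 5.74e-05, and adjusted p = 0.0654 with an estimated correlation). JAZ/TIFY repressors held 1 of 10 contigs higher and 7 lower (1 and 7 over the list alone, median -2.92, adjusted p = 5.35e-06) and ethylene genes 20 of 159 contigs higher and 53 lower (25 and 55 over the list alone, median -0.30, adjusted p = 0.000254). Those higher were the JAR enzyme A_08949, a lipoxygenase (A_02135) and TIFY 8 (A_16963), and on the terpene list below the exostosin contig (A_16212), all named after their values were seen. WRKY factors held 9 of 53 contigs higher and 22 lower (11 and 25 over the list alone, median -0.52, adjusted p = 0.000595, and adjusted p = 0.073 with an estimated correlation), and calcium genes 41 of 258 contigs higher and 70 lower (44 and 71 over the list alone, median -0.12, adjusted p = 0.0108, and adjusted p = 0.073 with an estimated correlation). Phenylpropanoid enzymes held 8 of 74 contigs higher and 24 lower (8 and 25 over the list alone, median -0.32, adjusted p = 0.0054), and terpene synthases 1 of 16 contigs higher and 8 lower (1 and 8 over the list alone, median -0.65, adjusted p = 0.00153, and adjusted p = 0.0836 with an estimated correlation). The clock list was higher at 24 h, with 46 of 122 contigs higher and 10 lower (49 and 12 over the list alone, median 0.40, adjusted p = 0.00256). So were histones and cell cycle genes, with 49 of 157 contigs higher and 11 lower (55 and 14 over the list alone, median 0.27, adjusted p = 0.00687, and adjusted p = 0.0907 with an estimated correlation). An ELF4-like clock gene (A_13962) was higher by 1.67 ± 0.12. Proteinase inhibitors did not pass, with 14 of 49 contigs higher and 7 lower (15 and 8 over the list alone, median 0.51, adjusted p = 0.184). The vascular (median 0.084, mean -0.10, test downward with adjusted p = 0.805), epidermis (median 0.16, mean -0.0042, test upward with adjusted p = 0.8), ribosomal (median -0.04, adjusted p = 0.399) and reference lists (median 0.16, adjusted p = 0.0603) did not pass either, though reference genes passed under normexp correction (0.0341) and in the deposited table (0.0389). In all, 15752 probes differed, 9279 higher at 24 h and 6473 lower, in 7795 contigs. Slide as a fixed block gave 12256, and within slide 1 and slide 2 alone 3182 (1157 higher, 2025 lower) and 2753 (601 and 2152). At 2-fold or more 2520 were higher and 3673 lower. Within slides the medians were -0.89 and -1.01 for jasmonate biosynthesis, -2.40 and -3.21 for JAZ/TIFY, -0.14 and -0.40 for ethylene, -0.48 and -0.46 for WRKY factors, -0.21 and -0.25 for phenylpropanoids, -0.55 and -1.23 for terpene synthases, 0.34 and 0.35 for the clock and 0.24 and 0.19 for histones. Under a slide block the JAZ/TIFY median was -2.86 and the clock median 0.33. Without the filter on dim probes the median over all probes was -0.0032 in place of 0.098.

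**Figure D3:**
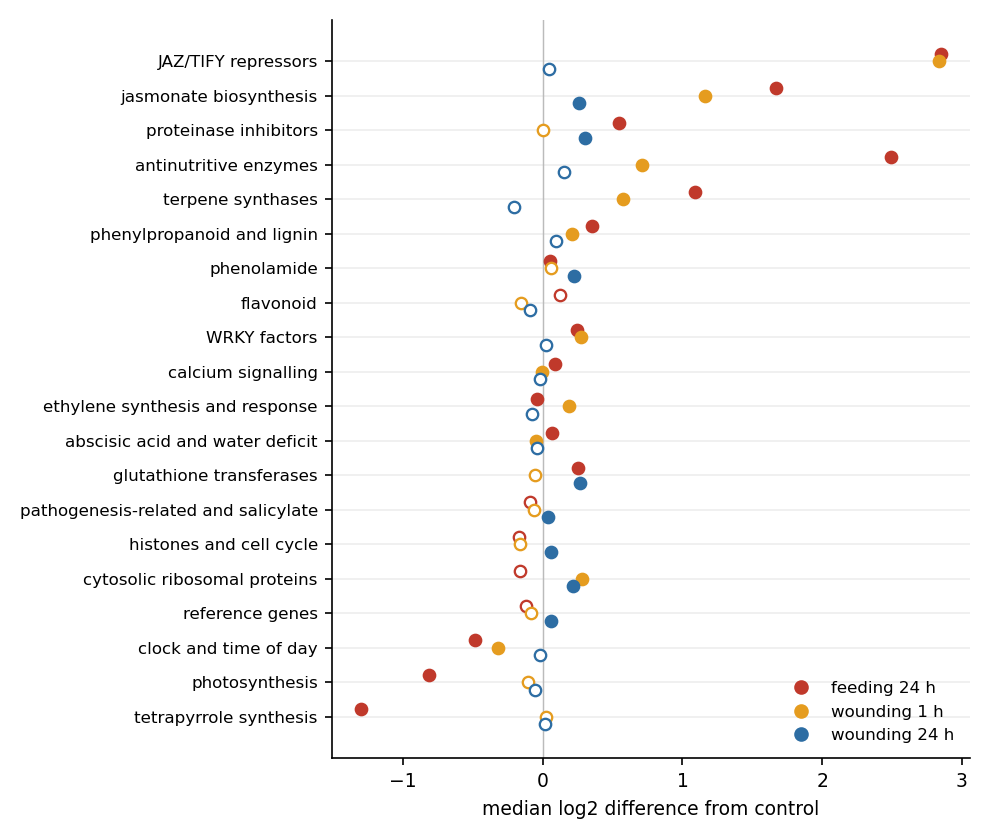
Median log2 difference of 20 gene lists (horizontal axis) in the 3 comparisons with control, with a filled point where the camera adjusted p was under 0.05 and an open one otherwise. Medians are of fitted values, and the tests of ethylene genes after feeding and of calcium and abscisic acid genes at 1 h went upward although their medians lay near or below 0. The jasmonate biosynthesis list stood at 1.67 after feeding, 1.16 at 1 h and 0.26 at 24 h after wounding, and the photosynthesis list at -0.81, -0.11 and -0.057.

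Responses were compared over the 47423 probes against shared controls, which alone links fold changes. Simulated groups without effect gave r = 0.50 and a covariance of 0.049. Splitting the controls also parts clones and may lower r. Feeding at 24 h and wounding at 24 h had r = 0.44, a covariance of 0.19 and, with the controls split between the comparisons, r from 0.22 to 0.32 and a mean covariance of 0.13. They shared 393 probes called higher (70.2 in independent lists) and 74 called lower (21.7), with 8 called in opposite directions (104), values for independent lists that leave out the shared controls, and the slope of wounding on feeding was 0.21. Wounding at 1 h and at 24 h had r = 0.24, a covariance of 0.096, and with split controls r from 0.047 to 0.16 and a mean covariance of 0.042. These shared 251 probes called higher (51.7 in independent lists) and 45 called lower (16.6), with 26 in opposite directions (79.5). Feeding at 24 h and wounding at 1 h, a pair added after the data were seen, had r = 0.64, a covariance of 0.54, and with split controls r from 0.48 to 0.58 and a mean covariance of 0.48. This pair shared 3599 probes called higher (901 in independent lists) and 3447 called lower (1440), with 497 in opposite directions (2280). JAZ1 (C_01875) stood at 6.22 ± 0.32 after feeding and 7.18 ± 0.32 at 1 h, the thiolase A_05722 at 4.31 ± 0.21 and 5.10 ± 0.21, and the cytokinin oxidase A_12406 at 3.95 ± 0.30 and 5.47 ± 0.30.

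**Figure D4:**
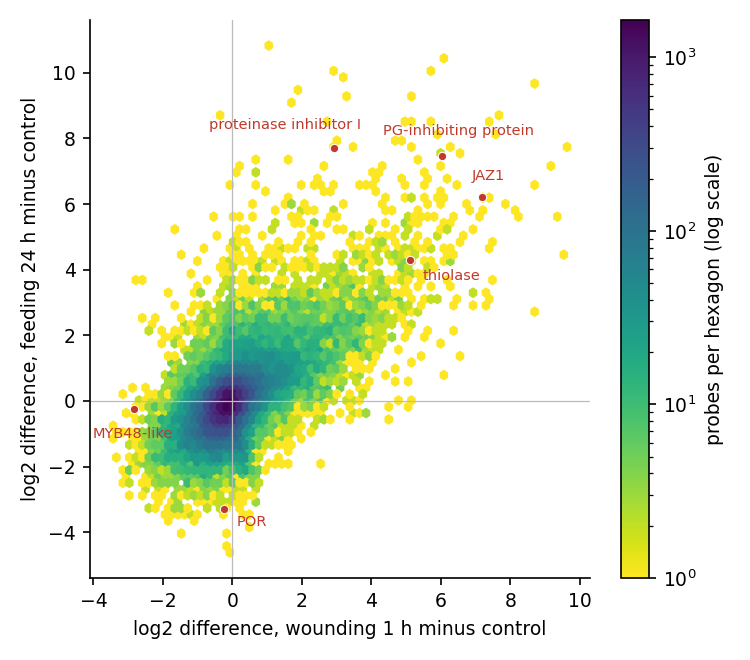
Log2 difference from control of each of the 47423 probes after wounding at 1 h (horizontal axis) and after feeding at 24 h (vertical axis), with darker shades for more probes per hexagon and red points for 6 contigs (PG, polygalacturonase; POR, protochlorophyllide reductase). The correlation was 0.64.

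The 4 clones were compared in a model of group and clone, which averages the clones over treatments, so a different response of a clone cannot be tested with 1 array per clone and group. Contig A_11110, a flavonoid 3-O-glucosyltransferase, an enzyme that adds sugar to flavonols, was well above background on no array of Grunewald and on all arrays of the other clones. By that probe it was at least 80.4-fold higher in Mehrow (2.15, log2 relative to the 75th percentile, mean of 4 arrays), with 0.97 in Siethen and 1.90 in Erkner. A Melmoth-type retrotransposon contig (C_04797) was likewise not measured in Grunewald and at least 8.97-fold higher in Mehrow, and a Mutator-like transposase (DC_01508), lowest in Grunewald, ranged over 8.77-fold. A CBS domain protein (A_16870, 10.4-fold) and a CYP72A-type cytochrome P450 (A_01891, 9.4-fold) were lowest in Mehrow. Adjusted p of these 5 lay between 1.78e-10 and 9.02e-09. In all, 13436 probes (28.3%) in 6729 contigs differed between clones, with a median range of 0.78 among them, and 4639 of them had a range of at least 1. A model with slide as a further term called 11272, and 8710 and 8469 were called without Siethen or Mehrow. The third principal component (9.09% of the variance) parted the arrays of Grunewald (-80.32 to -46.46) from the rest.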

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

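The tests of shared controls, renewed early response, clones on the same slides, brightness as the whole cause, mixed harvest times and vein or epidermis tissue were chosen after the result was seen.

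Arrays far from the other 3 of their group, by the gap to the nearest one over the whole range, were looked for in 16 groups of array measures, 112 of list medians and 378 of named contigs. They turned up in 1, 3 and 29 of these, and chance gives about 1 in 20 groups. The Mehrow array at 1 h had a median background of 19 where the other 3 had 18. Against the control mean, the phenylpropanoid median was low in control Grunewald (-0.0465), and the auxin median was high in control Siethen (0.0687) and low in Erkner after feeding (-0.25).

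Among control arrays (log2 signal relative to the 75th percentile) Siethen stood low for A_06085 (2.25), A_15832 (-3.05), C_05327 (-3.02) and DC_00335 (2.81). Grunewald stood low for A_13631 (-5.90), A_14912 (-2.75) and A_15475 (-5.15). Mehrow stood high for A_07337 (7.08) and C_00054 (2.63) and low for C_02477 (-1.39). After feeding, Siethen stood low for A_06058 (0.87) and A_11142 (2.84), Erkner low for A_03064 (3.73), and Grunewald low for A_02211 (4.92). Mehrow stood low for A_14310 (-3.18) and high for C_00658 (-1.31). At 1 h after wounding, Siethen stood high for A_16973 (-1.38) and Erkner low for A_03064 (3.30). Grunewald stood low for C_06700 (-2.79) and high for DC_00304 (3.11), and Mehrow low for A_02135 (-1.80). At 24 h, Siethen stood high for A_02734 (-4.91), A_07748 (1.59) and C_01732 (0.024), and Erkner low for A_05439 (0.83). Grunewald stood low for A_16675 (1.40) and high for A_16963 (-0.15), and Mehrow low for A_16024 (-1.82) and high for C_05327 (-2.86).

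Treatments that share a time point or a method differed by direct tests, with 15164 probes between feeding and wounding at 24 h and 15752 between the 2 times after wounding. At 1 h and 24 h after wounding 26 probes were called in opposite directions, 14 of them higher first, and how many the shared controls would leave by chance was not tested.

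Other splits of the arrays were counted for each comparison, and in each 1 of the 35 splits, the real one, gave as many calls. That is a share under 0.05 only where the pairing by clone is left aside. The real counts and the highest others were 17045 and 2 for feeding, 546 and 2 for wounding at 24 h, 12838 and 0 for wounding at 1 h, 15164 and 1 for feeding against wounding, and 15752 and 540 between the times. The split with 540 calls set the arrays of slide 1, by scan time, against the rest, and thereby both Grunewald arrays against both Mehrow arrays. That points to a structure by slide, scan or clone. With slide as a fixed block the real comparison gave 12256 calls. Among the 8 splits that part every clone's 2 arrays, as the real one does, the highest other was 0 in each comparison, but 8 are too few for a share under 0.05. For clones 1 of 100 regroupings, the real one, gave 13436 calls, and the highest other gave 1115.

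By correlation feeding resembled wounding at 1 h (0.64) more than at 24 h (0.435), but not by share of risers. Feeding shared 3599 of 5611 at 1 h and 393 of 437 at 24 h, counts that carry list length and the shared controls. Shared control arrays are argued against by a mean covariance of 0.484 with split controls, against 0.0488 for groups without effect. Slide is argued against by r = 0.429 between feeding on slide 1 and wounding at 1 h on slide 2, which share no array. Whether larvae that keep feeding may renew the early response stays open: of 2362 contigs higher at 1 h and lower again at 24 h after wounding, 63.5% were higher after feeding, and of 2551 that went the other way 47.1% were lower. These shares largely restate the similarity itself and so do not decide it.

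The clones differed at many probes. Sequence variants under single probes as the whole cause are argued against by a median r of 0.988 between the clone means of 936 probes with a range of at least 2 and another probe of the same contig. For 8.76% of these r was under 0.3, so variants could lie behind part of the calls. Slide is argued against because 75.7% of calls were kept with slide in the model, and because Siethen and Erkner, on the same slide in every group, differed at 5520 probes where other pairs differed at 5451 to 7458. Differences in ancestry or growth between clones stay open, untested.

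The photosynthesis fall after feeding (median -0.81, -1.13 to -0.483 by array, 95% bootstrap interval over contigs -0.895 to -0.74) was weighed against 3 explanations. Brightness-dependent scaling as the whole cause is argued against by 918 contigs of matched signal, at -0.213 (-0.251 to -0.17), -0.599 from the list. A partial share stays open, as matched contigs fell too. Controls of mixed harvest time are argued against by the same list at -0.0569 in wounding at 24 h. A larger share of vein and epidermis tissue in eaten leaves could lower it and cannot be told apart, since the vascular (-0.101 to 0.238) and epidermis (-0.337 to 0.056) intervals overlap, with medians -0.216 apart. Regulation by the plant stays open too.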

How the results depend on the processing

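Fits within slides, slide in the clone model, narrowed lists and the similarity of feeding and wounding at 1 h were chosen after the result was seen.

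Under quantile normalization, normexp correction, the deposited table, either filter, slide blocks, a trended and robust spread and the 2 groups alone, all counts stayed within 1.5 times. They ranged from 14740 to 17456 for feeding, 438 to 703 for wounding at 24 h, 10854 to 12999 for wounding at 1 h, 13371 to 15349 for feeding against wounding, 12256 to 16010 between the times and 11272 to 13951 for clones (the last 2 settings not run for clones, nor a random slide block). The clone as a block gave 22211, 3398, 18349, 20203 and 21974, and only wounding at 24 h moved beyond 1.5 times, since the block removes clone differences from the spread. Array weights moved it too, to 1348 (892 higher, 456 lower), and the cause was not tested. By construction, a 2-fold threshold gave fewer: 7814, 5790, 6761, 6193 and 4639 for feeding, wounding at 1 h, feeding against wounding, the times and the clones. So did an adjusted p under 0.01, with 234 for wounding at 24 h and 8355, 10090, 9614 and 7464 for the last 4. Within slide 1, with fewer arrays, 3334, 3, 3316, 3586 and 3182 probes were called, and within slide 2 10734, 13, 5398, 3529 and 2753, in the order feeding, wounding at 24 h, at 1 h, feeding against wounding and times. There a group with 1 array was assumed to vary like the others, and groups come in part from different clones.

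Without 1 array or clone the counts ranged from 13024 to 16637 for feeding, 208 to 508 for wounding at 24 h, 9437 to 11845 for wounding at 1 h, 11106 to 14584 for feeding against wounding, 9984 to 16769 between the times and 8469 to 9641 for clones. Wounding at 24 h fell to 361 and 322 without control Erkner or Grunewald. It gave 342, 332 and 358 without wounded Siethen, Erkner or Grunewald, and 264, 208, 226 and 289 without the clones Siethen, Erkner, Grunewald and Mehrow. The times fell to 9984 without Erkner, and clone differences to 8710 without Siethen and 8469 without Mehrow. Fewer arrays were tested in each.

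The similarity of feeding and wounding at 24 h (0.435) was 0.48 under quantile normalization, 0.472 in the deposited table, 0.268 with split controls, 0.52 over called probes and 0.414 to 0.475 without an array or clone. That of the 2 times (0.241) was 0.0925 with split controls and 0.171 to 0.302 without an array or clone. Feeding and wounding at 1 h (0.64) gave 0.601 under normexp, 0.541 with split controls, 0.671 over called probes and 0.617 to 0.656. Split controls remove shared arrays and part clones. No cause was tested.

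No called result changed direction. The chlorophyll and senescence list between the times, upward without a call (adjusted p = 0.881), was called downward by fry (0.00306). Of 217 named values, 6 were no longer called under quantile normalization, 16 under normexp, 12 in the deposited table, 25 in the 2 groups alone, 0 with the clone as a block, and 28 to 46 without a clone. Of 140 list tests, of which 60 were called, 1, 3 and 1 lost their call and 1, 2 and 2 gained one under the first 3 settings, 2 and 4 with the clone as a block, 1 and 9 with the mean over probes, 2 and 33 with fry for 1 direction, and 0 and 77 with mixed fry. With an estimated correlation 41 lost it and 0 gained one. Jasmonate biosynthesis at 24 h after wounding (adjusted p = 0.0272) lost its call under the mean over probes (0.0755), an estimated correlation (0.229), fry (0.122) and the narrowed list (0.126), and its lowest value was 0.00691 with the clone as a block. Signal over background limits the dimmest contigs: 12728 probes were too dim to test, and folds against unmeasured groups are bounds.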

Other observations

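The tests of annotation texts below were chosen after the main results were seen, and no cause was tested. Every annotation text shared by at least 15 contigs was tested for called contigs in each contrast with control and direction (156 texts, 936 Fisher tests, p adjusted over all). At 1 h after wounding, where 12.1% of other contigs or fewer were higher, 23 of 53 U-box proteins (adjusted p = 5.57e-06), which mark proteins for breakdown, 12 of 22 calmodulins (0.000302) and 25 of 58 ethylene-responsive factors (3.08e-06) were higher. After feeding 19 of 53 U-box proteins (0.0309) and 12 of 22 calmodulins (0.00502) were higher, against 16.8% and 16.9% of other contigs. Called lower at 1 h were 12 of 19 BEL1-like homeodomain proteins (0.000302), 10 of 19 FAR1-related factors of light signalling (0.00775) and 8 of 16 CONSTANS-like zinc fingers (0.0348), against 14.7% of other contigs. Of 15 SAUR genes of auxin-driven growth, 9 were lower at 1 h (0.00506) and 9 after feeding (0.0348).

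After feeding, of 55 contigs annotated as 50S ribosomal protein, the kind found in chloroplasts and mitochondria, 27 (49.1%) were lower, against 20.2% of other contigs (adjusted p = 0.000302), and so were 93 of 300 pentatricopeptide repeat proteins, which process organelle RNA (against 20.1% of other contigs, 0.000727). Most members of the second group were not called. Receptor-like kinases went both ways at 1 h, with 59 of 262 higher (0.000302) and 67 lower (0.00038), and 81 were lower after feeding (0.0025). At 24 h after wounding, 5 of 40 peroxidases (0.00453) and 4 of 15 glycine-rich proteins (0.0014) were higher.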
